A study of Mus musculus with 18 samples.

How the data were processed

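Bulk RNA sequencing of mouse colon and spinal dorsal horn was analysed, with 18 libraries in all. Each tissue had 3 groups of 3 libraries, named sham (sham surgery with control IgG), cancer (bone cancer with control IgG) and nivolumab (bone cancer with nivolumab), as the series' design text gives them. The labels state n = 3 per group and number the replicates 1 to 3, and say nothing further on how the libraries relate to separate animals. The p-values therefore measure only the spread between these samples, which may be partly technical.

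Total RNA was extracted with TRIzol and reverse-transcribed with a SmartScribe kit, and the cDNA was size-selected on beads before pooling, per the labels' protocols. Sequencing was on an Illumina NovaSeq 6000, per the series' design text. FastQC 0.11.5, Trimmomatic, HISAT2, StringTie and the GRCm38 build are named in the submitters' processing notes, without their order or further versions. The counting tool, the strand setting, the annotation version and any filter on genes are not given in the sources used here. The values deposited by the authors were whole-number counts per gene, with 1 table per tissue and no normalisation. The colon table held 14987 genes and that of the dorsal horn held 15193, of which 14770 were in both. Of 15410 symbols, 15408 were matched by name to the GENCODE annotation of GRCm38, from which gene coordinates were taken. No symbol belonged to the mitochondrial genome, and most class II MHC genes were not among the values analysed here. A count of 1 was rarer than a count of 2, with a median per library of 33 against 189 genes in the colon and 37 against 175 in the dorsal horn. The low counts are therefore not all single reads, and counting intervals may be too narrow. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and near-identical copies such as Hba-a1 and Hba-a2 may share reads.

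Total counts per library ran from 20896854 to 30803957 in the colon (median 26113440) and from 21855085 to 29071908 in the dorsal horn (median 26094884). A floor of 3 counts corresponded to 0.0950 to 0.149 CPM (counts scaled to library size) in the colon and 0.103 to 0.132 in the dorsal horn. The 10 most abundant genes took 5.59% to 7.78% of the counts in the colon and 5.13% to 8.11% in the dorsal horn. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. No pair of libraries of 1 group agreed within sampling noise, with a lowest chi-square per degree of freedom of 73.1 in the colon and 9.85 in the dorsal horn.

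Gene tests used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group and robust dispersion estimates. Each tissue was fitted with all 9 libraries, so that the 3 groups shared an estimate of the spread. The filter left 13445 genes in the colon and 13609 in the dorsal horn. The contrasts were cancer against sham, nivolumab against cancer and nivolumab against sham, all two-sided, and a joint test asked for any difference among the 3 groups. Adjusted p-values followed Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. CPM values are means ± SD of n = 3 libraries, and log2 CPM used a prior count of 2. Fitted folds of genes near 0 counts depend on the prior count, and for these the text gives a ratio of summed CPM with its 95% counting interval, or a bound from a floor of 3 counts over the group. The biological coefficient of variation was 0.376 in the colon and 0.170 in the dorsal horn. Responses in the 2 tissues were compared by an interaction term in 1 fit of all 18 libraries over 14164 genes.

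Gene lists for pathways, cell types and possible admixed tissues were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. There were 42 lists for the colon and 36 for the dorsal horn, 21 of them shared. A list with at least 3 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, and adjusted over the lists of the tissue. Camera with an estimated correlation and fry were alternatives. The number of members past 0.05 is given over all genes tested and adjusted over the list alone.

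Genes were named by a rule. It took the 10 largest rises and the 10 largest falls among genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the libraries of the 2 groups. Where fewer than 10 genes passed, those with the smallest unadjusted p were taken up to 10. In each list up to 4 members past the threshold with the smallest adjusted p were named, or else 1 or 2 members with the smallest p. Gene models without a proper symbol and antigen receptor segments were counted and not named. A few genes that the rule names are not reported here. The genes of the PD-1 axis Pdcd1, Cd274 and Pdcd1lg2 were always included. For the comparison of tissues, the named genes were those with the smallest interaction p among genes already named for that contrast. This reading was settled after the interaction results were seen.

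The test was tried on simulated counts with the real means and library sizes, in which 200 genes were changed. For the colon contrast of cancer and sham (13445 genes), 15% of 100 genes changed 2-fold and 64% of 100 changed 4-fold were recovered, and 3 of 82 calls were wrong. For the dorsal horn contrast of cancer and sham (13609 genes), 75% and 99% were recovered and 13 of 187 calls were wrong.

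Alternatives were edgeR with DESeq2 size factors, with upper-quartile factors, without a filter on low counts and with only the 2 groups compared. DESeq2 1.42.0, limma voom, a block for the replicate number and fits without each library of the groups compared in turn were also run. Further fits were chosen after seeing the data. They left out each library of the third group, which only shares the spread, colon sham 3 and cancer 2, or dorsal horn sham 3 and cancer 3, or used the mean of a ganglion marker list as a covariate in the dorsal horn. Another had a block for dorsal horn replicate numbers in the comparison of tissues. The labels do not say that a replicate number marks a shared animal, litter or day. Among the same-numbered dorsal horn libraries of cancer and nivolumab, deviations from the group means correlated in all 3 pairs (0.190 to 0.276, against −0.323 to 0.111 for other numbers), so this contrast was read as paired by the data alone, and blocked values stand beside its results where they change a call. Correlations of fold changes between contrasts that share libraries were set beside 20 simulations of unchanged groups. Microbiome data named in the series' title were not analysed here.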

Results

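Transcripts were counted in the colon and the spinal dorsal horn, the part of the cord that receives sensory input, of mice from 3 groups. Sham mice received control IgG, cancer mice carried a bone tumour and received control IgG, and nivolumab mice carried the tumour and received nivolumab, an antibody developed against human PD-1. The series' title names acute bone cancer pain and blockade of PD-1, an inhibitory receptor of T cells. Each group had 3 libraries per tissue. Fold changes compare the first group named with the second, values are CPM ± SD (n = 3) unless stated, and adjusted p-values of genes are from edgeR.

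The dorsal horn libraries differed in markers of neighbouring tissues. Scn10a, a sodium channel of sensory neurons, had 89.4 CPM in sham 3 and 102.5 in cancer 3, against 0, 0.0789, 0.105 and 0.114 in the other sham and cancer libraries. In the nivolumab libraries it had 307.5, 205.1 and 400.3 CPM. The mean of 14 dorsal root ganglion neuron markers was 3.91 log2 CPM in sham 3, 4.02 in cancer 3 and 5.11 to 5.92 in the nivolumab libraries, and it lay between −1.42 and −1.01 in the other 4. Schwann cell markers had means of 4.19 to 4.51 with nivolumab and 1.80 to 3.60 in the other groups. Skeletal muscle markers ranged from −0.47 (cancer 3) to 6.53 (nivolumab 2), with all 3 nivolumab libraries at 3.17 or above. Red blood cell markers had means of 5.84 to 6.58 in sham and 3.80 to 4.83 in the other 6 libraries. The first principal component held 41.9% of the variance and placed nivolumab libraries at 36.8 to 47.9 and the others at −32.6 to 2.72.

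**Figure D1:**
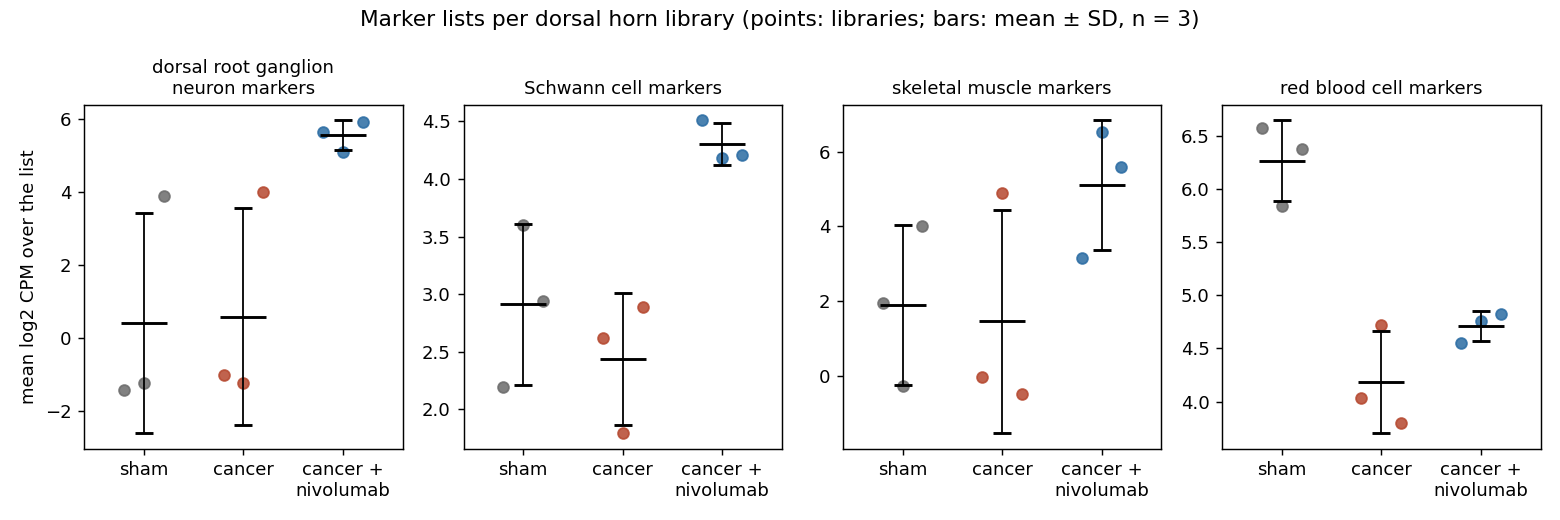
Mean log2 CPM over the members of 4 marker lists in each dorsal horn library (points), with the mean ± SD of each group (bars, n = 3). The ganglion panel shows sham 3 (3.91) and cancer 3 (4.02) near the nivolumab libraries (5.11 to 5.92), and the red blood cell panel shows sham (5.84 to 6.58) above the rest.

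Cancer was compared with sham in the dorsal horn. Trh, the precursor of thyrotropin-releasing hormone, rose 3.50-fold, from 3.00 ± 0.643 to 10.5 ± 2.04 CPM (log2 fold change 1.81, SE 0.24, adjusted p = 0.0248, chromosome 6, 92242061 to 92244650). Wdfy1, an adaptor in Toll-like receptor signalling, rose 2.24-fold from 28.9 ± 1.92 to 64.7 ± 3.09 CPM (1.16, SE 0.07, adjusted p = 0.000231, chromosome 1, 79702262 to 79776143). Mobp, a component of central myelin, fell from 8975 ± 816.6 to 4771 ± 295.4 CPM (−0.91, SE 0.08, adjusted p = 0.00352, chromosome 9, 120149707 to 120181484). Aim2, a sensor of cytosolic DNA, fell from 10.7 ± 1.86 to 3.37 ± 0.505 CPM (−1.67, SE 0.18, adjusted p = 0.0105, chromosome 1, 173350879 to 173466040). Aim2 lies in a cluster of related genes, so its counts are uncertain.

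In all, 44 of 13609 genes passed the threshold, 13 higher and 31 lower, and 12 of them changed at least 2-fold. Other rises were Adi1 (1.07, adjusted p = 0.0283), the GABA-A receptor subunit Gabra2 (1.06, adjusted p = 0.05 after rounding, from 57.9 ± 12.1 to 121 ± 22.8 CPM), the kinase Camk4 (1.00), Lyplal1 (1.15), Tmem144 (1.03), Pcdhb3 (0.94) and Riok3 (0.64). Other falls were the phosphatase Acp1 (−0.99, adjusted p = 0.0105), the myelin gene Mal (−0.91, adjusted p = 0.0423), Cldn14 (−0.89) and Plat, tissue plasminogen activator (−0.83, adjusted p = 0.0241). Each of these had no overlap between the 3 cancer and 3 sham libraries, which held for 16.8% of all genes against 10% by chance. At an unadjusted p under 0.05 there were 1783 genes (680 by chance). The count of 44 fell to 2 without sham 1, 11 without sham 2 and 28 without cancer 2, and rose to 78 without sham 3 and 125 without cancer 1. Nivolumab libraries only share the spread in this contrast, yet it was 2 without nivolumab 1, 9 without nivolumab 2 and 19 without nivolumab 3. A fit of only these 2 groups called 2 genes, Wdfy1 and Mobp, the only ones among 23 named genes called here that passed in all 15 alternatives and without any 1 nivolumab library.

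**Figure D2:**
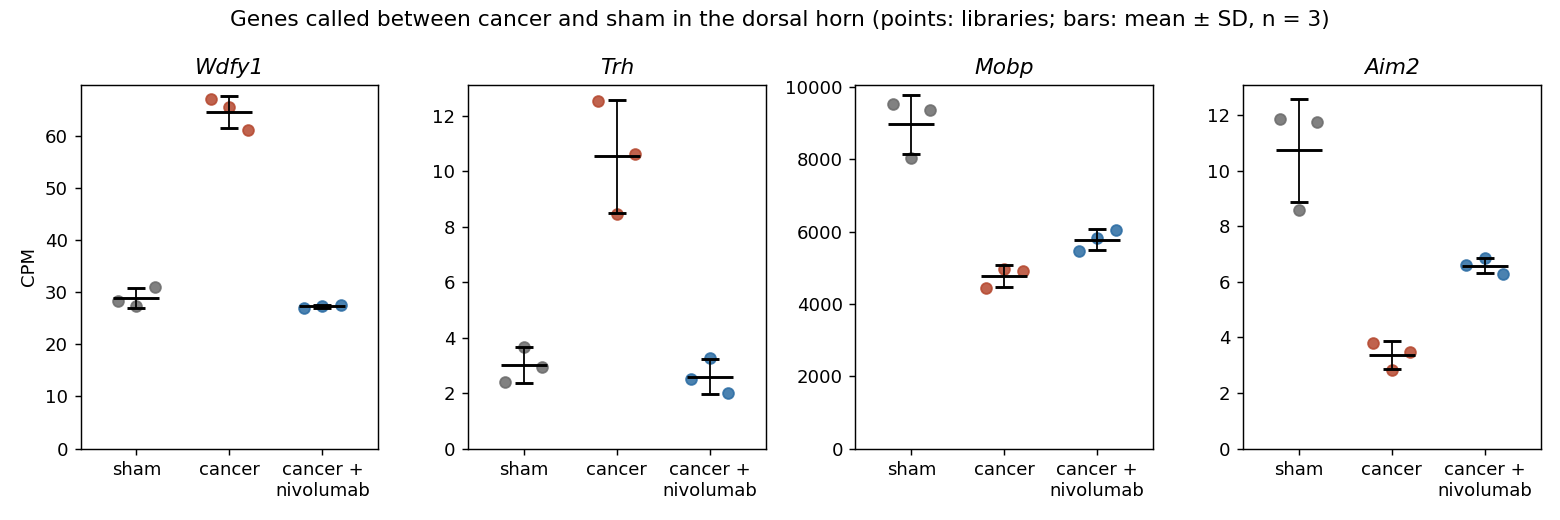
CPM of Wdfy1, Trh, Mobp and Aim2 in each dorsal horn library (points) with group means ± SD (bars, n = 3), on linear axes. Wdfy1 lay at 61.21 to 67.15 CPM in cancer and at 27.00 to 31.05 in both other groups, while Mobp was highest in sham.

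Of 7 red blood cell markers 4 fell and 3 did not pass, with 6 lower when adjusted over the list alone. Alas2, the first enzyme of haem synthesis in red cells, fell from 21.2 ± 6.88 to 2.83 ± 1.01 CPM (−2.90, adjusted p = 0.0183). The globin genes Hbb-bs (−2.73), Hba-a1 (−2.59) and Hba-a2 (−2.57), of which the last pair is nearly identical, had adjusted p-values of 0.0257 to 0.0305. The list median was −2.59 (adjusted p = 1.35e-29 with the preset correlation and adjusted p = 0.0225 with an estimated correlation). No member passed without any 1 of sham 1, nivolumab 1 and nivolumab 2, without nivolumab 3 there was 1, without cancer 1 there were 2, and none passed without sham 3 and cancer 3 together.

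Of 15 oligodendrocyte and myelin genes 3 fell (Mobp, Mal and Mbp) and 12 did not pass, 5 fell when adjusted over the list alone, and all 15 had negative fold changes (median −0.64, adjusted p = 1.98e-18). This list test gave adjusted p = 0.192 with an estimated correlation. Mbp, a major protein of central myelin, fell from 30670 ± 2637 to 18420 ± 3002 CPM (adjusted p = 0.0356). Without sham 1, sham 2 or any 1 nivolumab library 1 myelin gene passed, and without sham 3 and cancer 3 together 8 did. All 3 cancer libraries had mean myelin list levels (8.12 to 8.96 log2 CPM) below those of sham 1 and 2 (9.47 and 9.52), with sham 3 at 8.87. Of 72 ribosomal protein genes 2 fell, Rpl3 (−0.64, adjusted p = 0.0248) and Rps7 (−0.39, adjusted p = 0.0423), 70 did not pass and 13 fell when adjusted over the list alone (median −0.10, adjusted p = 8.52e-09, and adjusted p = 0.517 with an estimated correlation). None passed without sham 1, cancer 2, cancer 3 or any 1 nivolumab library, and 1 without sham 2 or sham 3.

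Among neuronal lists, 1 of 20 excitatory markers rose (Trh), 1 of 21 glutamate receptors rose (Grik3, 0.60, adjusted p = 0.05 after rounding) and 1 of 18 GABA and glycine receptors rose (Gabra2). Their medians were 0.18, 0.11 and 0.12, with adjusted p-values of 0.00146, 0.00623 and 0.0164, and adjusted p = 0.470, 0.481 and 0.517 with an estimated correlation. All 3 genes were lost without sham 1, sham 2 or nivolumab 1, Grik3 and Gabra2 also without cancer 2, cancer 3, nivolumab 2 or nivolumab 3, and Grik3 without sham 3. None of the 18 inhibitory neuron markers passed, although 17 had positive fold changes (median 0.25, adjusted p = 7.03e-05), and all 8 opioid genes were positive (median 0.30, adjusted p = 0.00411), 2 of them past the threshold over the list alone. Both lists had adjusted p = 0.333 with an estimated correlation. The opioid receptor Oprk1 had 0.56 (adjusted p = 0.126) and the inhibitory gene Slc6a5 0.24 (adjusted p = 0.202). Immediate early genes, which mark recent cell activity, had 0 of 23 past the threshold and 7 over the list alone (median 0.38, adjusted p = 3.15e-06, and adjusted p = 0.246 with an estimated correlation), with Egr1 at 23.6 ± 1.83 in sham and 40.5 ± 8.95 CPM in cancer (0.78, adjusted p = 0.126).

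Apart from the myelin genes, the glial and immune lists held no member past the threshold over all genes. Astrocyte markers had a median of −0.21 (5 of 14 lower over the list alone, adjusted p = 4.00e-05, and adjusted p = 0.0912 with an estimated correlation). Microglial markers were negative in all 23 members (median −0.27, adjusted p = 0.000206, and adjusted p = 0.517 with an estimated correlation), with the complement gene C1qb at −0.52 (adjusted p = 0.0857). Oligodendrocyte precursor markers were negative in all 10 (median −0.29, adjusted p = 0.00211), and cell cycle genes had a median of −0.39 (adjusted p = 0.000321), with adjusted p = 0.481 and 0.192 with an estimated correlation. The 6 tested T and NK cell markers were all positive (median 0.97, adjusted p = 0.000807, and adjusted p = 0.192 with an estimated correlation), with Il7r at 1.64 (adjusted p = 0.183). Oxidative phosphorylation genes (median −0.11, adjusted p = 5.02e-05), class I antigen presentation (0.23, adjusted p = 0.0153), endothelial markers (−0.22, adjusted p = 0.0234) and interferon response genes (0.13, adjusted p = 0.0257) also passed. These 4 lists had adjusted p = 0.481, 0.481, 0.617 and 0.652 with an estimated correlation, and the endothelial test had adjusted p = 0.0516 with the ganglion score as a covariate. The class I and interferon tests did not pass without sham 3 and cancer 3 together (adjusted p = 0.204 and 0.467). In all 18 lists passed. The ganglion list (median 0.05, adjusted p = 0.804) and Schwann list (−0.28, adjusted p = 0.358) did not. Test and median differed in sign for skeletal muscle (median 0.60, mean 0.64, tested lower, adjusted p = 0.804), and median and mean for cytokines (−0.12 and 0.07, adjusted p = 0.358).

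The comparison of nivolumab with cancer asked what the antibody changed in tumour-bearing mice. In the dorsal horn 20 of 27 interferon response genes rose. Ifit1, an antiviral gene induced by interferon, rose 5.99-fold from 3.34 ± 0.944 to 20.002 ± 6.27 CPM (log2 fold change 2.58, SE 0.29, adjusted p = 0.00171, chromosome 19, 34640871 to 34650009). Oasl2 rose 4.54-fold (2.18, SE 0.22, adjusted p = 0.00149, chromosome 5, 114896936 to 114912234). Stat2, a transcription factor of the interferon pathway, rose from 40.2 ± 2.30 to 64.2 ± 6.81 CPM (0.68, adjusted p = 0.00216, chromosome 10, 128270559 to 128292849), and the GTPase Igtp rose 3.17-fold (1.67, adjusted p = 0.00274, chromosome 11, 58199556 to 58207591).

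Of 27 interferon response genes 20 rose, 7 did not pass and none fell, with 22 higher over the list alone (median 1.20, adjusted p = 6.55e-16, and adjusted p = 0.329 with an estimated correlation). Without nivolumab 1, 12 passed. List means were 2.63 to 3.25 log2 CPM in nivolumab and 1.45 to 1.98 in the other 6 libraries. Ganglion markers were high in the same 3 libraries, and with the ganglion score as a covariate, a fit chosen after seeing the data, 19 of these 20 genes still passed. Of 12 class I antigen presentation genes 2 rose, the light chain B2m (1.67-fold, from 81.2 ± 4.98 to 136 ± 5.92 CPM, adjusted p = 0.00111) and Psme2 (0.34, adjusted p = 0.014), and 3 over the list alone (median 0.27, adjusted p = 0.0658). Cd74, the chaperone of class II MHC, rose from 6.76 ± 2.38 to 18.1 ± 2.80 CPM (1.42, adjusted p = 0.0281) and was 1 of only 2 tested class II genes, so that list had no test. This Cd74 call was lost without any 1 of cancer 1, cancer 3 and the 3 nivolumab libraries, and 1 class I gene passed without nivolumab 1.

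**Figure D3:**
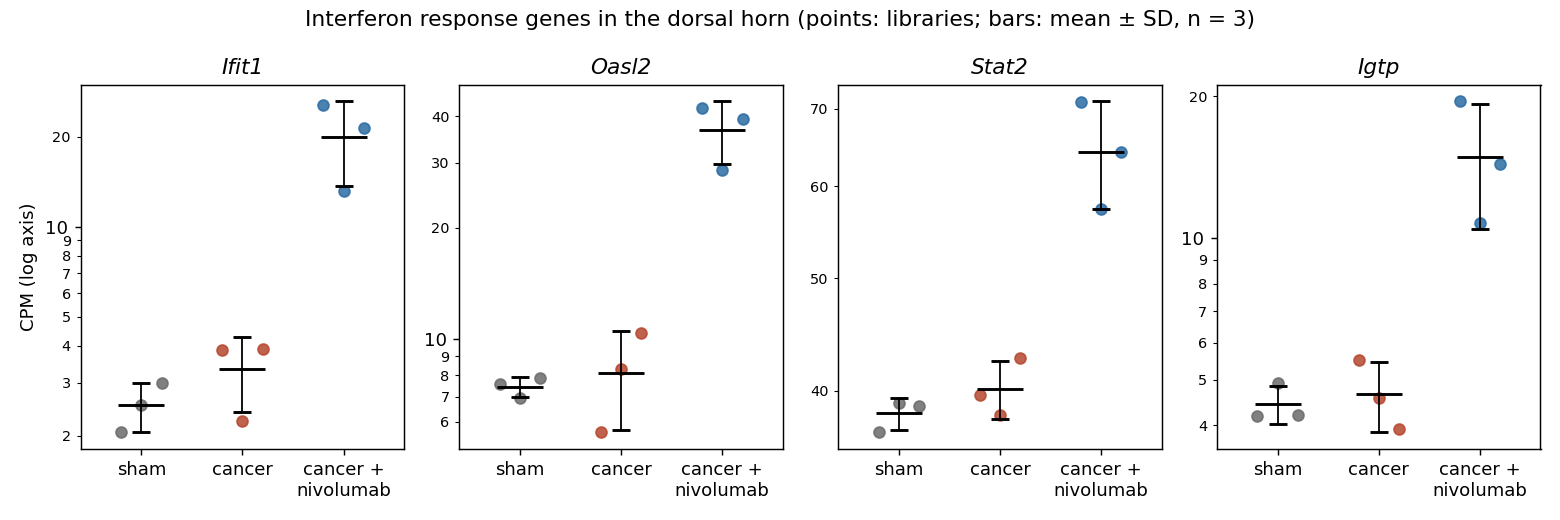
CPM (log axes) of Ifit1, Oasl2, Stat2 and Igtp in each dorsal horn library (points) with group means ± SD (bars, n = 3). The nivolumab libraries of Ifit1 (13.16 to 25.48 CPM) lie above all sham and cancer libraries (2.055 to 3.886 CPM).

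Of 18 inhibitory neuron markers 8 fell and 10 did not pass, 9 fell over the list alone, and the median was −0.55 (adjusted p = 1.09e-07, and adjusted p = 0.329 with an estimated correlation). Slc6a5, the neuronal glycine transporter, fell from 556 ± 51.4 to 367 ± 14.3 CPM (−0.60, SE 0.07, adjusted p = 0.00187), and Slc32a1, which loads GABA and glycine into vesicles, fell by 0.56 on the log2 scale (adjusted p = 0.00217). Of 18 GABA and glycine receptor genes 8 fell and 10 did not pass, 10 over the list alone (median −0.37, adjusted p = 3.20e-05, and adjusted p = 0.404 with an estimated correlation). They included Gabra2 (121 ± 22.8 to 61.5 ± 1.34 CPM, adjusted p = 0.00763), Gabra3 (−0.48), Gabra5 (−0.42) and the chloride transporter Slc12a5 (729 ± 53 to 499 ± 35.7 CPM, adjusted p = 0.00216). Of 21 glutamate receptors 8 fell and 13 did not pass, with 12 lower and 2 higher over the list alone (median −0.35, adjusted p = 3.20e-05, and adjusted p = 0.404 with an estimated correlation), among them Grin2d (−0.58), Grik3 (−0.73) and Grin1 (−0.53). Of 8 opioid genes 4 fell over all genes and over the list alone (median −0.36, adjusted p = 0.0117, and adjusted p = 0.404 with an estimated correlation), the peptide precursors Penk (196 ± 4.58 to 139 ± 14.9 CPM, adjusted p = 0.00899) and Pnoc (−0.56) and the receptors Oprl1 (−0.43) and Oprk1 (−0.73). Excitatory markers did not pass (1 of 20 higher and 3 lower, median −0.25, adjusted p = 0.127), and among them Trh fell from 10.5 ± 2.04 to 2.59 ± 0.633 CPM (adjusted p = 0.00191). The substance P receptor Tacr1 fell (−0.68) and its ligand gene Tac1 rose (0.92, adjusted p = 0.023). The Tac1 call was lost without cancer 1, cancer 2, nivolumab 1 or nivolumab 3 and with the ganglion covariate (0.43 to 1.05 over the alternatives). The covariate also ended the Pnoc call and the opioid list's (adjusted p = 0.196), and 5 GABA and glycine genes then passed. Without nivolumab 1, 5 inhibitory, 4 GABA and glycine and 5 glutamate genes passed. The last 2 lists had 5 and 5 without cancer 2, and 4 and 5 without nivolumab 3. Excitatory markers had 2 past without cancer 2 and 2 without nivolumab 1, and 2 higher and 5 lower with the replicate number as a block. Ganglion, Schwann cell and muscle markers were high in the same nivolumab libraries.

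**Figure D4:**
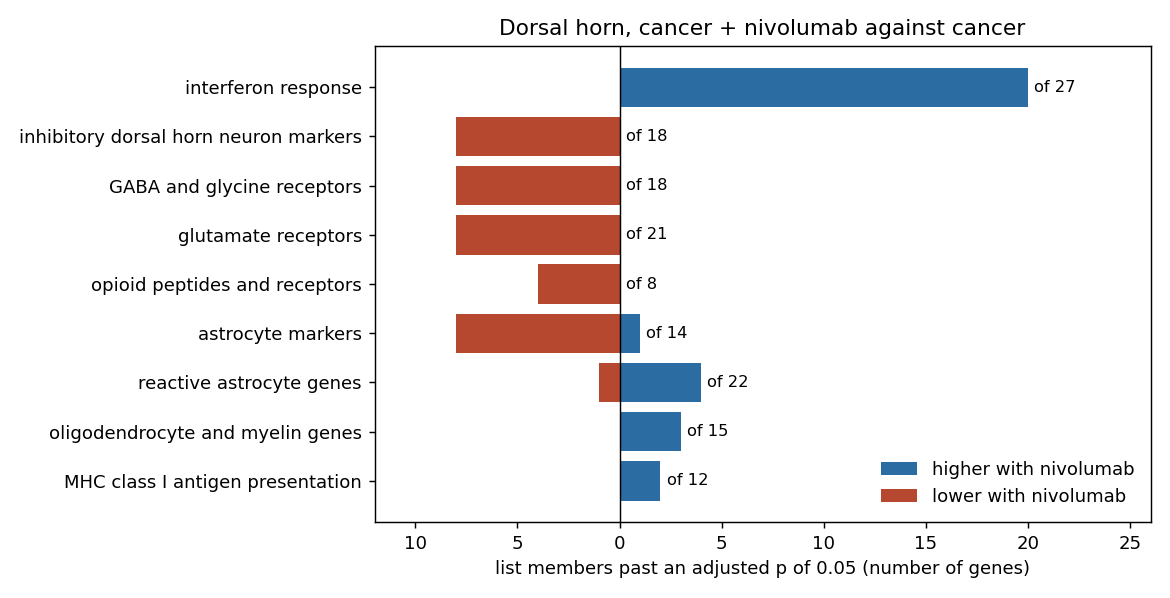
Number of members of 9 gene lists past an adjusted p of 0.05 in nivolumab against cancer in the dorsal horn, with bars to the right for higher and to the left for lower members and the number tested beside each. Interferon response genes had 20 of 27 higher, and the inhibitory, GABA and glycine, and glutamate lists had 8 lower each.

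Among glia, 8 of 14 astrocyte markers fell, 1 rose and 5 did not pass (9 and 1 over the list alone, median −0.34, adjusted p = 0.000992, and adjusted p = 0.329 with an estimated correlation). They included Fgfr3 (−0.49) and the glutamate transporter Slc1a2 (−0.36, adjusted p = 0.0179), and the 8 falls became 4 without cancer 2, 5 without cancer 3 and 2 without nivolumab 1. Of 22 reactive astrocyte genes 4 rose (Vim, S1pr3, Ggta1 and Stat3) and 1 fell (Lcn2). Vim, an intermediate filament gene, rose from 78.3 ± 13.3 to 145 ± 15.2 CPM (adjusted p = 0.00427), and the list had a median of 0.51 (adjusted p = 0.0198, and adjusted p = 0.656 with an estimated correlation). Only 2 of these 5 passed without cancer 2, without nivolumab 1 or without nivolumab 3, and with the replicate block 9 members rose and 2 fell. The myelin genes Mal (0.64), Mbp (0.45) and Mobp (0.28) rose with adjusted p-values of 0.0176 to 0.0393, and 12 of 15 did not pass (median 0.63, adjusted p = 6.91e-05, and adjusted p = 0.630 with an estimated correlation). No myelin gene passed without nivolumab 1, 1 passed without cancer 3, nivolumab 2 or nivolumab 3, and Mobp was lost with upper-quartile factors or without sham 1. With the replicate block 9 passed. Slc1a2, Ggta1, Stat3 and Mobp lost their calls with the ganglion covariate, as did both astrocyte lists (adjusted p = 0.196 and 0.503), and 12 myelin genes rose.

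Pmp2, a myelin protein of peripheral nerve, had 13.7 ± 3.97 against 0.402 ± 0.351 CPM (adjusted p = 0.0127). It was near 0 counts in cancer, and its log2 fold change ran from 4.50 to 7.80 over the alternatives. Trpm8, the cold receptor of sensory neurons, had 9.01 ± 1.69 against 0.926 ± 0.845 CPM (adjusted p = 0.0275). Dhh, a signal from Schwann cells, had 14.1 ± 2.34 against 2.11 ± 1.46 CPM (adjusted p = 0.0183), a call lost without nivolumab 1 or nivolumab 3 and with the ganglion covariate. Myoc (4.25), Cnmd (3.35), Rec8 (3.28), Col28a1 (3.19), Lum (3.01), Prokr1 (2.76) and Stbd1 (2.67) completed the 10 largest rises, with adjusted p-values of 0.00608 (Cnmd) to 0.0333 (Myoc). The largest falls were Lrg1 (−3.28, from 10.6 ± 8.20 to 1.08 ± 0.477 CPM, adjusted p = 0.014), Lcn2 (−3.28, adjusted p = 0.0491), Pla2g4e (−2.94), Plin4 (−2.82), Gabrr2 (−2.19), Trh (−2.02), Hif3a (−2.00), Vwf (−1.89), Ttc34 (−1.80) and Dsc3 (−1.74). With the replicate block Pla2g4e (−2.71, adjusted p = 0.0532) and Plin4 (−2.63, adjusted p = 0.0504) did not pass. Without nivolumab 1, of these 20 genes only Pmp2, Cnmd, Stbd1, Trh and Ttc34 passed. All 14 ganglion neuron markers were positive, with 2 past the threshold, Trpm8 and Calcb (1.47, adjusted p = 0.00832; list median 3.06, adjusted p = 0.000191, and adjusted p = 0.638 with an estimated correlation). Of these 1 passed without any 1 of cancer 1, cancer 2 and the nivolumab libraries, and 4 markers passed without sham 3 and 6 with the replicate block. Of 9 Schwann cell markers 3 rose (Pmp2, Dhh and Gldn, median 1.25, adjusted p = 0.00023, and adjusted p = 0.484 with an estimated correlation), with 5 past without cancer 3 and 1 without nivolumab 1 or nivolumab 3. All 10 skeletal muscle markers were positive, none past the threshold (median 2.27, adjusted p = 0.0195, and adjusted p = 0.701 with an estimated correlation). Of 16 fibroblast and matrix genes 4 rose and 1 fell (median 0.43, adjusted p = 0.0962), with Postn at 2.16 and Col3a1 at 2.28 (with the replicate block adjusted p = 0.0559). Only 1 of these 5 passed without cancer 2, 3 without cancer 3 and none without nivolumab 1 or 3. Rec8, Prokr1, Dsc3, Postn and Gldn lost their calls with the ganglion covariate, the Schwann and muscle lists had adjusted p = 0.132 and 0.346, and 2 ganglion markers were higher and 5 lower. Without sham 3 and cancer 3 together all 14 passed.

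Glucocorticoid response genes were negative in all 17 members, and 3 fell, Plin4, Hif3a and Zbtb16 (−0.77; median −0.81, adjusted p = 9.65e-05, and adjusted p = 0.638 with an estimated correlation). None of these passed without cancer 2 or nivolumab 1, and 1 passed without any 1 of sham 1, sham 2, cancer 3, nivolumab 2 and nivolumab 3. Without cancer 1 there were 8, and with the replicate block 5. Circadian clock genes had 2 of 18 lower, Tef among them, and 9 over the list alone (median −0.27, adjusted p = 0.00394, and adjusted p = 0.404 with an estimated correlation). Cell cycle genes had 1 of 26 higher, Top2a (2.48; median 0.42, adjusted p = 0.0199), and the unfolded protein response had 2 of 20 higher, Atf4 (0.43) and Pdia3 (0.41; median 0.19, adjusted p = 0.0233). Their values with an estimated correlation were adjusted p = 0.404 and 0.701. No clock gene passed without sham 1, cancer 3 or any 1 nivolumab library, 4 did without sham 3 and 6 with the replicate block, and the Tef call was also lost without cancer 1 or cancer 2. Without cancer 1, 3 cell cycle and 4 unfolded protein response genes passed, and without cancer 3, 2 cell cycle genes. The unfolded protein response had 4 without sham 3, and with the replicate block the lists had 2 and 4. Microglial markers (median 0.29, adjusted p = 0.0582, and adjusted p = 0.0302 with the replicate block), red blood cell markers (0.54, adjusted p = 0.0681) and T and NK cell markers (−1.11, adjusted p = 0.125, Il7r −1.77) did not pass as lists in the fit without the block. The Il7r call was lost without any 1 library of the 2 groups except cancer 1 (2 genes). With the ganglion covariate Il7r and Zbtb16 lost their calls and the cell cycle list its own (adjusted p = 0.356), while 8 glucocorticoid, 5 clock, 9 unfolded protein response and 14 microglial genes passed. Ribosomal protein genes had a median of −0.03, a mean of 0.00 and a test toward lower values (adjusted p = 0.463).

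In all 2345 of 13609 genes passed, 1175 higher and 1170 lower, with 317 changed at least 2-fold. Of all genes 40.1% had no overlap between the 2 groups, against 10% by chance, and 4650 had an unadjusted p under 0.05. The count was 771 without nivolumab 1, 964 without nivolumab 3 and 1144 without cancer 2. With the ganglion covariate 1513 of the 2345 genes passed in the same direction, among 3126 called. Of 90 named genes called here 34 passed in all alternatives and without any 1 sham library, among them Ifit1, Oasl2, Stat2, Igtp, B2m, Slc6a5, Slc12a5, Gabra2, Penk, Trh and Pmp2, and 38 passed without nivolumab 1.

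Against sham, 17 of 27 interferon response genes rose in the dorsal horn of nivolumab mice. Ifit1 rose 7.89-fold from 2.52 ± 0.470 to 20.002 ± 6.27 CPM (2.98, SE 0.30, adjusted p = 0.0038) and Oasl2 4.93-fold (2.30, SE 0.22, adjusted p = 0.00365). Cd74 rose 5.97-fold from 3.02 ± 1.52 to 18.1 ± 2.80 CPM (2.58, SE 0.37, adjusted p = 0.0087). Olfml2a, which encodes an extracellular protein, rose 5.92-fold from 1.86 ± 0.285 to 11.1 ± 0.687 CPM (adjusted p = 0.0038). Fgfr3, a receptor of astrocytes, fell from 338 ± 22.7 to 205 ± 6.40 CPM (−0.72, SE 0.06, adjusted p = 0.00149), and Tac1 rose 3.16-fold from 15.8 ± 4.90 to 50.2 ± 8.29 CPM (adjusted p = 0.00711).

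Of 27 interferon genes 17 rose and 10 did not pass, 22 rose over the list alone and all 27 were positive (median 1.25, adjusted p = 3.00e-29, and adjusted p = 0.106 with an estimated correlation). Of these 9 passed without sham 1, 6 without nivolumab 1 and 10 without nivolumab 3. Of 12 class I genes 3 rose (B2m 0.49, Tapbp 0.32 and Psme2 0.36) and 8 over the list alone (median 0.34, adjusted p = 5.55e-05, and adjusted p = 0.322 with an estimated correlation), with 1 past without sham 1, nivolumab 1 or nivolumab 3 and 5 without cancer 1 or cancer 3. Of 14 astrocyte markers 7 fell, including Ntsr2 (−0.44), Glul (−0.69) and Aldoc (−0.53), 7 did not pass and 9 fell over the list alone (median −0.40, adjusted p = 1.62e-12). The astrocyte test held with adjusted p = 0.0114 with an estimated correlation, and 3 members passed without nivolumab 1. Of 22 reactive astrocyte genes 4 rose (Vim 1.21, S1pr3 1.95, Stat3 0.56 and Ggta1 0.98, median 0.40, adjusted p = 0.00129, and adjusted p = 0.551 with an estimated correlation), with 1 past without sham 1 or nivolumab 1 and 2 without sham 2 or nivolumab 3. Tapbp, Stat3 and Ggta1 lost their calls with the ganglion covariate, and the class I and reactive astrocyte tests had adjusted p = 0.150 and 0.423.

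Red blood cell markers fell in 5 of 7 cases (median −1.97, adjusted p = 2.71e-09, and adjusted p = 0.180 with an estimated correlation), with Alas2 at 4.12 ± 1.11 against 21.2 ± 6.88 CPM (adjusted p = 0.00703) and Hbb-bs at 101 ± 17.0 against 397 ± 94.4 (adjusted p = 0.0124). Only 1 passed without nivolumab 1 and 3 without nivolumab 3. Of 18 inhibitory markers 4 fell, of 18 GABA and glycine receptor genes 5, and of 21 glutamate receptors 4, with medians of −0.27, −0.20 and −0.22 and adjusted p-values of 0.00104, 0.00171 and 0.00326, and each with adjusted p = 0.551 with an estimated correlation. They included Slc12a5 (−0.42), Gabra5 (−0.40) and Grin1 (−0.41). None of these 3 lists kept a member past the threshold without nivolumab 1. Without nivolumab 3 they had 1, 2 and 1, and without sham 1 they had 2, 3 and 2. Without sham 2 the last pair had 3 and 2. None of these list tests passed with the ganglion covariate (adjusted p = 0.0712 to 0.261).

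Ganglion markers (median 3.15, all 14 positive, adjusted p = 5.27e-06), Schwann cell markers (1.03, adjusted p = 0.000228) and skeletal muscle markers (2.92, adjusted p = 0.0078) were higher with nivolumab. These 3 lists had adjusted p = 0.551, 0.551 and 0.677 with an estimated correlation. Glucocorticoid genes (−0.79, adjusted p = 1.75e-05), circadian genes (−0.17, adjusted p = 0.0078) and ribosomal protein genes (−0.15, adjusted p = 3.56e-07) were lower, with adjusted p = 0.551, 0.551 and 0.627 with an estimated correlation. Immediate early genes (0.34, adjusted p = 0.0087) and the unfolded protein response (0.20, adjusted p = 0.00709) were higher, with adjusted p = 0.551 and 0.677 with an estimated correlation. The early genes Nr4a1 (0.86) and Nr4a2 (0.98) passed the threshold, Nr4a2 not without cancer 1 or cancer 2. Neither passed without sham 1, sham 2 or nivolumab 1, 1 early gene did without sham 3, nivolumab 2 or nivolumab 3, and 4 did without cancer 3. With the ganglion covariate Nr4a1 and Nr4a2 lost their calls and the early list's test turned toward lower values (median 0.15, adjusted p = 0.839). The Schwann and muscle tests then had adjusted p = 0.201 and 0.246, and 27 ribosomal protein genes were lower. Oxidative phosphorylation genes were tested as lower (adjusted p = 0.00505, and adjusted p = 0.674 with an estimated correlation) with a median of −0.09 and a mean of 0.02. Myelin genes did not pass (median 0.03, mean −0.03, adjusted p = 0.25), while Mobp fell from 8975 ± 816.6 to 5782 ± 295 CPM (adjusted p = 0.00522). Opioid genes had a median of −0.08 and a mean of 0.01, with the receptor Oprl1 (−0.38) and Penk (−0.37) lower, 1 of them past without any 1 sham library, any 1 cancer library or nivolumab 2 and none without nivolumab 1 or nivolumab 3. In all 1158 genes passed, 635 higher and 523 lower, with 191 changed at least 2-fold and 35.2% not overlapping, against 10% by chance. The count was 95 without nivolumab 1, 310 without nivolumab 3, 228 without sham 1 and 652 without sham 2. With the ganglion covariate 656 of the 1158 genes passed in the same direction, among 2144 called. Of 69 named genes called here 16 passed in all alternatives and without any 1 cancer library, the 10 interferon, antigen presentation and glial genes Ifit1, Oasl2, Stat2, Igtp, B2m, Cd74, Fgfr3, Ntsr2, Glul and Vim among them.

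The other large rises against sham were Prokr1 (3.17), Col28a1 (3.17), Sostdc1 (2.79), Dhh (2.77), Postn (2.71), Stbd1 (2.70) and P2ry2 (2.39). The other large falls were Slc4a1 (−3.10), Gabrr2 (−2.46), Ptgs2 (−1.76), Acss3 (−1.59), Uts2b (−1.27) and Slc24a4 (−1.26). Adjusted p-values of these rises and falls were 0.00583 (Slc24a4) to 0.0431 (Uts2b). Sostdc1 and Slc24a4 passed in all 15 alternatives, and the calls of all the others were lost without nivolumab 1 and without nivolumab 3, those of Dhh, Postn, P2ry2, Slc4a1 and Uts2b also with the ganglion covariate. Within the PD-1 axis, Cd274, the ligand PD-L1, had 5.48 ± 0.588 CPM in sham, 7.14 ± 0.545 in cancer and 8.13 ± 1.39 in nivolumab (chromosome 19, 29367455 to 29388095). Its log2 fold changes were 0.38 for cancer against sham, 0.19 for nivolumab against cancer and 0.57 for nivolumab against sham, with adjusted p-values of 0.365, 0.445 and 0.062. The phosphatase Ptpn11 fell against sham (−0.56, adjusted p = 0.0118), not without sham 1 or nivolumab 1, and the list of 10 tested checkpoint genes did not pass in any contrast. Pdcd1, which encodes PD-1, had 0 to 14 counts per library and was not tested, and Pdcd1lg2 had 0 to 6. Any difference among the 3 groups was found for 1889 dorsal horn genes. That count was 452 without nivolumab 1, 629 without nivolumab 3, 1243 without nivolumab 2, 1086 without sham 1 and 1139 without cancer 2.

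Colon libraries differed in muscle, dividing cell and neutrophil markers. The mean of 14 smooth muscle markers was 5.99 log2 CPM in sham 3, 8.26 and 9.72 in the other sham libraries, 8.29 to 9.86 in cancer and 7.21 to 7.71 in nivolumab. Cell cycle genes were lowest in cancer 2 (2.63) and nivolumab 1 (3.67), with 5.20 to 6.26 elsewhere. Neutrophil markers had means of −2.59 to −1.21 in sham, −1.09 to 2.70 in cancer and 0.91 to 3.26 in nivolumab. The first principal component (41.9% of the variance) ran from sham 3 (−88.0) to cancer 2 (99.6).

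**Figure D5:**
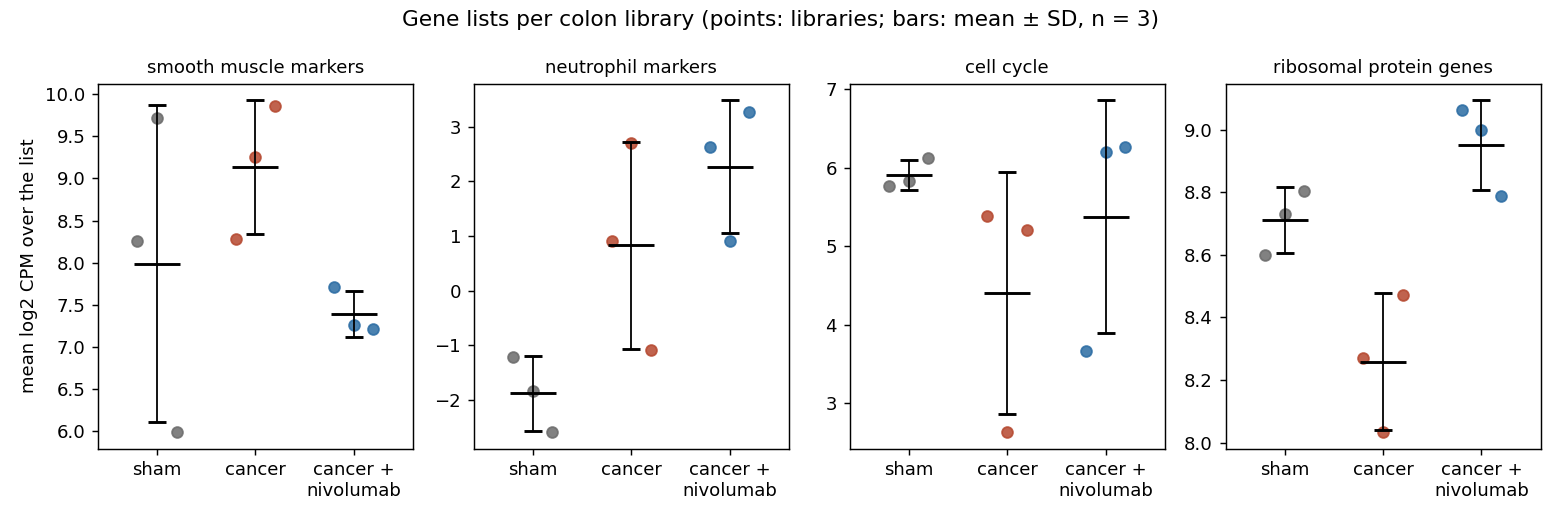
Mean log2 CPM over the members of 4 gene lists in each colon library (points), with the mean ± SD of each group (bars, n = 3). Smooth muscle markers ranged from 5.99 (sham 3) to 9.86 (cancer 3), and neutrophil markers were below −1 in all 3 sham libraries.

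In the colon of cancer mice the genes with the smallest p included Ly6d, a surface protein of epithelia, at 206 ± 134 against 7.32 ± 1.92 CPM in sham (28.2-fold), and Tnf, the inflammatory cytokine, at 23.9 ± 6.25 against 5.57 ± 0.0929 CPM (4.30-fold). Lpo, lactoperoxidase, had 381 ± 193 against 26.9 ± 10.8 CPM (14.2-fold), and Psca had 25.5 ± 23.2 against 0.1003 ± 0.112. Rpl29, a ribosomal protein gene, had 214 ± 32.8 against 489 ± 47.2 CPM, Gsta3, a glutathione transferase, had 5.004 ± 1.37 against 20.2 ± 4.27, Zfp868 had a log2 fold change of 1.53 and Entpd4 one of −0.99. Cps1, the first enzyme of the urea cycle, had 3 counts in cancer and 2832 in sham, a ratio of 721 (counting interval 247 to 3499). These 9 genes did not overlap between groups and shared an adjusted p of 0.0748, which missed the threshold. None of 13445 genes passed with edgeR or limma voom, 1468 had an unadjusted p under 0.05 (672 by chance), 19.3% did not overlap (10% by chance), and DESeq2 called 379. Without cancer 3 edgeR called 9 genes, and without cancer 2 it called 1.

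In all 16 lists passed for cancer against sham in the colon, and none did with an estimated correlation (adjusted p = 0.624 to 0.740) or by fry. Neutrophil markers were positive in 10 of 11 members, 7 of them past the threshold over the list alone (median 4.91, adjusted p = 1.60e-07, and adjusted p = 0.624 with an estimated correlation). Mmp8, a neutrophil collagenase, had 0 counts in sham and 340 in cancer, at least 143-fold higher against a floor of 3 counts over the group, and the list median was 4.91 also with Mmp8 and Ngp, the members at 0 in sham, at their bounds. All 17 glucocorticoid response genes were positive, 8 past the threshold over the list alone (median 1.02, adjusted p = 6.94e-09), with Zbtb16 at 60.8 ± 24.6 against 6.58 ± 3.71 CPM (adjusted p = 0.11). All 71 ribosomal protein genes were negative, 30 over the list alone (median −0.45, adjusted p = 1.85e-24). All 26 cell cycle genes (median −1.11, adjusted p = 5.08e-09) and all 20 cholesterol synthesis genes (−0.40, adjusted p = 4.11e-07, 4 over the list alone) were negative. B and plasma cell markers had a median of −0.86 (adjusted p = 1.60e-07, 4 of 14 lower over the list alone), with the antibody joining chain gene Jchain at 169 ± 83.8 against 1029 ± 117.2 CPM (adjusted p = 0.076). Stem cell markers (−0.86, adjusted p = 9.03e-05), goblet cell genes (−0.45, adjusted p = 0.0224), macrophage markers (−0.30, adjusted p = 0.0078) and oxidative phosphorylation genes (−0.13, adjusted p = 0.00329) were lower. Higher lists were enteric neurons (1.30, adjusted p = 0.00113), smooth muscle (0.57, adjusted p = 0.00253), circadian genes (0.51, adjusted p = 0.00329), class I antigen presentation (0.36, adjusted p = 0.00096), Toll-like receptor signalling (0.36, adjusted p = 0.0073) and interferon response (0.21, adjusted p = 0.0258). Antimicrobial genes did not pass (median 0.54, adjusted p = 0.064), with 4 higher and 1 lower over the list alone and Nos2, inducible nitric oxide synthase, at 325 ± 64.5 against 50.7 ± 18.2 CPM (adjusted p = 0.181). The interferon median turned to −0.19 without cancer 1. Without sham 3 and cancer 2 together the enteric neuron median turned to −0.28 (adjusted p = 0.333) and that of oxidative phosphorylation to 0.083 (adjusted p = 0.206), and the smooth muscle and goblet cell tests did not pass (adjusted p = 0.394 and 0.368).

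Nivolumab was then compared with cancer in the colon. Rpl29 had 590 ± 54.9 against 214 ± 32.8 CPM in cancer (2.76-fold, adjusted p = 0.139), Gsta3 21.5 ± 2.81 against 5.004 ± 1.37 (4.29-fold, adjusted p = 0.141) and Ly6d 13.8 ± 3.76 against 206 ± 134 (adjusted p = 0.141). Chrm3, a muscarinic acetylcholine receptor, had 1.15 ± 0.546 against 8.25 ± 1.93 CPM (−2.83), and Ciita, the activator of class II MHC, had 31.9 ± 2.29 against 84.8 ± 14.5 (adjusted p = 0.182). Psca (−7.54), Entpd4 (0.98), Zfp868 (−1.47), Spats2l (−0.79) and Reep6 (1.41, adjusted p = 0.196) were the others of the 10 smallest p. None of 13445 genes passed with edgeR or limma voom, 1323 had an unadjusted p under 0.05, 15.2% did not overlap (10% by chance), and DESeq2 called 181. Without cancer 3 edgeR called 2.

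In all 21 lists passed for this contrast, and none with an estimated correlation (adjusted p = 0.366 to 0.700) or by fry. All 71 ribosomal protein genes were positive, 67 of them past the threshold over the list alone (median 0.71, adjusted p = 6.69e-65), as were 55 of 56 oxidative phosphorylation genes (0.29, adjusted p = 1.17e-07), all 26 cell cycle genes (0.93, adjusted p = 1.74e-05) and all 16 xenobiotic and bile acid genes (0.61, adjusted p = 0.0004). All 14 smooth muscle markers were negative (median −1.85, adjusted p = 1.44e-10), as were all 11 tuft cell markers (−1.27, adjusted p = 1.78e-07), with Dclk1, which marks these chemosensory cells, at 15.8 ± 5.15 against 34.7 ± 6.21 CPM (adjusted p = 0.353). Immediate early genes (−0.50, adjusted p = 1.16e-07), interferon response genes (−0.33, 1 of 27 positive, adjusted p = 1.74e-05), class I antigen presentation (−0.39, adjusted p = 0.000727), glucocorticoid genes (−0.31, adjusted p = 0.00484), circadian genes (−0.40), adipocyte markers (−1.42), goblet cell genes (−0.27), endothelial markers (−0.55) and enteric neurons (−0.90) were lower. Cytokines (0.56, adjusted p = 0.00285), cholesterol synthesis (0.20, adjusted p = 0.0039), stem cell markers (0.63, adjusted p = 0.00838), enteroendocrine markers (0.57), red blood cell markers (1.40) and neutrophil markers (1.30) were higher, these last 3 and the lists given above without a p with adjusted p = 0.0195 to 0.0479. Pax4, an enteroendocrine transcription factor, had 55 counts against 2 in cancer, a ratio of 21.6 (counting interval 5.69 to 182.5). The cell cycle mean was, as given above, lowest in cancer 2 and next lowest in nivolumab 1. Without cancer 2, 12 lists passed. The enteric neuron median turned to 0.06 without cancer 2. Without sham 3 and cancer 2 together 13 lists passed, that median was 0.08, and the endothelial test turned toward higher values (median −0.29, adjusted p = 0.662). Barrier genes had a median of 0.01 and a mean of −0.02 (adjusted p = 0.5).

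Against sham, all 11 neutrophil markers were positive in the colon of nivolumab mice and 8 passed over the list alone (median 6.54, adjusted p = 8.47e-19, and adjusted p = 0.346 with an estimated correlation). The median was 6.54 also with Mmp8 and Ngp, at 0 counts in sham, at their bounds. S100a8, a calcium-binding protein abundant in neutrophils, had 25.9 ± 18.9 against 0.137 ± 0.238 CPM (adjusted p = 0.372), and the chemokine receptor Cxcr2 had 219 counts against 2 in sham, a ratio of 112 (counting interval 30.7 to 934). Clca1, a secreted goblet cell protein, had 845 ± 257 against 16710 ± 2391 CPM (adjusted p = 0.331). Among the 10 smallest p, Fam221a had 4.12 ± 1.20 against 32.8 ± 8.82 CPM and Chrm3 1.15 ± 0.546 against 11.8 ± 2.13, both with an adjusted p of 0.0892. S100a11 (1.40), C1qtnf3 (−3.45), Dio2, which activates thyroid hormone (4.78, from 0.422 ± 0.257 to 11.6 ± 3.32 CPM, adjusted p = 0.213), Igf2r (−0.88), Cish (−1.05), Dgat2 (1.59) and Clca2 (−4.58) were also among them. None of 13445 genes passed with edgeR or limma voom, 867 had an unadjusted p under 0.05, 14.9% did not overlap (10% by chance), and DESeq2 called 147. Only these 2 groups in the fit gave 7, and the fits without cancer 1 and cancer 2 gave 1 and 3.

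In all 17 lists passed for nivolumab against sham in the colon, and none with an estimated correlation (adjusted p = 0.346 to 0.865) or by fry. Tuft cell markers (median −1.65, 6 of 11 lower over the list alone, adjusted p = 3.09e-11), goblet cell genes (−0.42, 4 of 14, adjusted p = 3.65e-08) and B and plasma cell markers (−0.22, 4 of 14, adjusted p = 2.57e-06) were lower. Immediate early genes (−0.42, adjusted p = 9.60e-05), mast cell markers (−1.12, adjusted p = 0.000237), smooth muscle (−1.24, adjusted p = 0.000833), cholesterol synthesis (−0.14, adjusted p = 0.00661), fibroblasts (−0.35, adjusted p = 0.015) and cell cycle genes (−0.08, adjusted p = 0.0303) were also lower. Ribosomal protein genes (0.26, adjusted p = 4.76e-10), cytokines (0.64, 4 of 25 higher over the list alone, adjusted p = 2.13e-06), glucocorticoid genes (0.68, adjusted p = 9.60e-05), red blood cell markers (1.95, adjusted p = 0.000333), lipid oxidation (0.29, adjusted p = 0.00995), Toll-like receptor signalling (0.29, adjusted p = 0.0241) and oxidative phosphorylation (0.15, adjusted p = 0.032) were higher. Without sham 3 and cancer 2 together the cell cycle test had adjusted p = 0.284. Without nivolumab 1 the cell cycle median turned to 0.26 and the oxidative phosphorylation median to −0.02. Without sham 2 the smooth muscle median was −0.19 and its test turned toward higher values. Antimicrobial genes had a median of 0.25, a mean of −0.16 and a test toward higher values (adjusted p = 0.63), and T and NK cell markers a median of 0.09 and a test toward lower values (adjusted p = 0.63).

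Across the 3 colon groups, 2 genes differed in the joint test, Ly6d among them (adjusted p = 0.0308, chromosome 15, 74762056 to 74763620). The number was 7 without cancer 3, 5 without cancer 2, 1 without cancer 1 and 0 without any 1 of the other 6 libraries. In the PD-1 axis, Cd274 had 42.2 ± 11.97 CPM in sham, 54.0 ± 25.9 in cancer and 27.6 ± 7.47 in nivolumab, with adjusted p-values of 0.702, 0.495 and 0.857 for the 3 contrasts in the order above. Pdcd1 had log2 fold changes of 1.10, −0.52 and 0.58 and Pdcd1lg2 −0.97, −0.09 and −1.06, with adjusted p-values of 0.487 to 0.959. Cd274 for cancer against sham changed sign without cancer 2 (−0.06), and Pdcd1lg2 for nivolumab against cancer without cancer 1 (0.12), cancer 2 (0.02) or nivolumab 1 (0.24).

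The same contrasts were compared between tissues. The response to cancer differed for 22 of 14164 genes (3 with the dorsal horn replicate number as a block), 12 with the higher value in the colon. Named genes among them were Aim2 (0.30 in the colon and −1.67 in the dorsal horn, adjusted p = 0.00862), Psca, Lpo (3.84 and −0.09), Cps1 and Jchain (−2.57 and 0.78). Of these only Aim2 kept its call with the block. The response to nivolumab against cancer differed for 18 genes (71 with the block), 14 with the lower value in the colon. Among the 18 were Igtp (−0.91 in the colon and 1.68 in the dorsal horn, adjusted p = 0.0255), Chrm3 (−2.89 and −0.16) and Rps15a (0.75 and −0.17). For nivolumab against sham it was 26 genes, 19 with the lower value in the colon, among them Chrm3, Dio2 (4.80 and −0.47), Cish, a suppressor of cytokine signalling (−1.07 and 0.87), Olfml2a (−0.89 and 2.58) and Igf2r (−0.89 and 0.03). Across genes, which are not independent replicates, fold changes in the 2 tissues had correlations of 0.111, 0.0501 and −0.0706. At an unadjusted p under 0.05 there were 1538, 2325 and 1799 genes. The count of 22 was 6, 40, 14 and 93 without colon sham 1, sham 2, cancer 2 and cancer 3, and 3, 3, 6, 3 and 5 without dorsal horn sham 1, 2 and 3 and cancer 2 and 3. The count of 18 was 98, 136, 138, 7 and 30 without colon cancer 1, cancer 3 and nivolumab 1, 2 and 3. Without dorsal horn cancer 2, cancer 3 and nivolumab 1, 2 and 3 it was 5, 34, 1, 10 and 6. The count of 26 was 6, 4, 48 and 13 without colon sham 1, sham 2, nivolumab 1 and nivolumab 3. Without the 3 sham and then the 3 nivolumab libraries of the dorsal horn it was 3, 3, 5, 5, 7 and 6.

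To ask whether nivolumab moved what cancer moved, the 2 contrasts were compared. Both share the cancer libraries, which gives a negative correlation with no effect at all. In the dorsal horn, all 13 genes higher in cancer than sham, Trh, Wdfy1 and Gabra2 among them, fell with nivolumab, and 20 of the 31 lower genes rose, where 1.12 and 2.68 are the overlaps of independent lists and 0.05 was the simulated mean. Wdfy1 fell by 1.24 (adjusted p = 0.000124), Adi1 fell by 1.29 and Acp1 rose by 1.00 (adjusted p = 0.00169). Across all genes r was −0.421 and the covariance −0.0858, against −0.493 and −0.0516 in simulations, and r was −0.174 without sham 3 and −0.667 without cancer 3. In the colon r was −0.633 and the covariance −0.337, against −0.506 and −0.128. Nivolumab against sham and against cancer shared 486 higher and 357 lower genes in the dorsal horn (54.8 and 45.0 for independent lists), with r = 0.797 and a covariance of 0.244, against 0.506 and 0.0532 simulated. Cancer and nivolumab, both against sham, shared 14 lower genes (1.19 for independent lists), with r = 0.212 and a covariance of 0.0400 against 0.499 and 0.0523. In the colon these pairs gave r = 0.321 and 0.530 (simulated 0.498 and 0.496). The simulated values leave out real effects and the overlaps of independent lists leave out the shared libraries. With 3 libraries the shared group could not be split, so part of any excess may come from the shared libraries.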

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

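The tests of the difference between tissues were planned. The counts of sample splits, the fits of cancer against sham without a nivolumab library, the block in the comparison of tissues, and all tests of explanations except that of ganglion tissue carried along with the cord, were chosen only after the result was seen. Each group held 3 libraries, so no library was tested for lying far from its group.

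Responses differed between colon and dorsal horn in the interaction test for 22 genes in cancer against sham, 18 in nivolumab against cancer and 26 in nivolumab against sham. The values below are log2 fold changes in the colon minus those in the dorsal horn. For cancer against sham they were 1.97 for Aim2 (adjusted p = 0.00862), 7.84 for Psca (adjusted p = 0.0187), 3.93 for Lpo (adjusted p = 0.0214), −10.53 for Cps1 (adjusted p = 0.0318) and −3.35 for Jchain (adjusted p = 0.0335). For nivolumab against cancer they were −2.73 for Chrm3 (adjusted p = 0.0173), −2.59 for Igtp (adjusted p = 0.0255), 0.92 for Rps15a (adjusted p = 0.0405) and −6.77 for Psca (adjusted p = 0.0439). For nivolumab against sham Chrm3 had −3.35 and Cish −1.94 (both with an adjusted p of 0.00803), and Dio2 had 5.26 (adjusted p = 0.00989). Clca2 had −10.80, C1qtnf3 −3.74 and Igf2r −0.93 (all with an adjusted p of 0.026), Fam221a −3.31 (adjusted p = 0.0343), and Dgat2 1.79 and Olfml2a −3.47 (both with an adjusted p of 0.0471). The values of Psca, Cps1 and Clca2 rest on groups near 0 counts, depend on the prior count and are no bounds. Without 1 library the 3 counts ran from 3 to 93, 1 to 138 and 3 to 48. Of 100 splits of the libraries 2, 4 and 1 gave as many genes, the real one included, with 73, 586 and 13 as the highest of the other splits. The shares exclude chance in no contrast. For nivolumab against sham, mixing its dorsal horn groups adds their difference to the spread, which can lower counts. For cancer against sham another split gave 73. For nivolumab against cancer 8 of the 80 splits parting all 3 same-numbered dorsal horn pairs gave as many (highest other 586). Such splits were not run for the other contrasts. With the dorsal horn numbers as a block the counts were 3, 71 and 33. For the 71, 6 of the 80 splits gave as many (highest other 396). Values of 73 and 586, several times the real counts, point to a structure of the samples beyond their groups.

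Ganglion transcripts were high in dorsal horn sham 3, cancer 3 and all 3 nivolumab libraries. Ganglion tissue carried along with the cord, the tissue next to it, would bring further ganglion genes into sham 3 and cancer 3. Of 27 tested genes of a further list 26, or 96.3%, were higher in both libraries than in the other libraries of their group, where 11.1% is the share by chance. That was the prediction, and it leaves carried tissue as the candidate explanation for these 2 libraries. Switching on of ganglion genes by nivolumab is excluded as the whole cause, because sham 3 and cancer 3, which had none, lay at least 4.91 log2 units above the other 4 libraries without it, while a part in the nivolumab libraries stays open.

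Interferon response genes were higher in the dorsal horn with nivolumab. Of the 20 genes called against cancer (12 without nivolumab 1), 19 were still called with the ganglion score as a covariate. The list median was 1.20 before and 1.27 after. The ganglion marker Trpm8 and the Schwann cell marker Pmp2 also kept their calls with this covariate. It therefore cannot exclude ganglion tissue as a cause, which stays open. Blood carried along is excluded as the whole cause, because the red blood cell list had a median of −1.97 in nivolumab against sham while the interferon list was higher, and a part of it stays open against cancer, where the red blood cell list had 0.54 (adjusted p = 0.0681). A response to nivolumab remains as a hypothesis found and tested on the same data, with the lowest nivolumab library 0.646 log2 units above the highest of the other 6. Other tissue carried along, such as the muscle that was high in the same libraries, was not tested and stays open.

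The 44 genes that differed between cancer and sham in the dorsal horn (2 to 125 without any 1 library) mostly went back with nivolumab. Less red blood cell RNA than in sham, which cancer and nivolumab libraries shared, is excluded for the 13 genes higher in cancer, as their median of 1.03 was 0.066 in nivolumab against sham (upper quartile 0.092). It stays open for the 27 lower genes outside the red blood cell list, whose median of −0.57 was −0.26 in that contrast, with 10 still lower past the threshold. A genetic difference between the mice stays open. Of these 40 genes 11 had another within 5 Mb (median 8 and highest 24 in 10000 random sets, permutation p = 0.193). Of the 37 tested in the colon, 26 changed in the same direction there. A response to the tumour that nivolumab removed also stays open, because the 75% of the 44 genes that went back rest on 2 contrasts that share the cancer libraries.

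Splits of 6 libraries into 3 and 3 number 10 and are too few for a share under 0.05. The real counts of genes in the colon were 0, 0 and 0 in the order of the contrasts above, with 0, 3 and 0 as the highest of the other splits. For gene lists in the colon they were 16, 21 and 17, with highest others of 25, 22 and 24. In the dorsal horn the real counts of genes were 44, 2345 and 1158, with highest others of 256, 0 and 1. The 256 genes separated sham 1, sham 2 and cancer 1 from sham 3, cancer 2 and cancer 3, several times the real count of 44, which points to a structure of the samples. Lists in the dorsal horn numbered 18, 15 and 17, with highest others of 18, 16 and 14. For nivolumab against cancer the real split parts all 3 same-numbered pairs, and the other splits that part 3 gave 0 genes and 9, 14 and 15 lists, against 2345 and 15, while the rest part 1 pair. In the joint test of 3 groups 2 of 100 splits gave the 2 colon genes (highest other 2). So small a count, 0 without any 1 of 6 libraries, cannot exclude chance. For the 1889 dorsal horn genes 1 of 100 splits gave as many (highest other 1722). Of 100 parting all 3 same-numbered pairs 2 did (highest other 3028, with sham and cancer parted as for the 256 genes). Both highest others kept the nivolumab libraries together and mixed sham with cancer, so the shares cannot exclude chance between those 2 groups.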

How the results depend on the processing

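The fits without a library of the group not compared, the block between tissues, without colon sham 3 and cancer 2, without dorsal horn sham 3 and cancer 3, and with a ganglion covariate are the tests of this part chosen only after the result was seen. Over all alternatives, values of named genes kept their direction and side of the threshold 2621 times, lost the call 654 times, gained it 40 times and changed direction 6 times. Gene list calls were kept 864 times, lost 317 times and reversed 13 times. Of counts and correlations, 176 stayed within 1.5 times and 115 did not. In the dorsal horn counts, DESeq2 size factors gave 44, 2330 and 1139 genes for cancer against sham, nivolumab against cancer and nivolumab against sham, of which 44, 2314 and 1131 were among the 44, 2345 and 1158. Limma voom gave 49, 2404 and 1214 (43, 2235 and 1116 shared). No scaling moved the median of all genes by over 0.1. Where a value below has no cause named, the cause was not tested. Depth limits genes near the floor of 3 counts, for which fitted folds depend on the prior count.

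DESeq2 called 379, 181 and 147 colon genes in the 3 contrasts, 366 and 1936 dorsal horn genes against sham, 447 and 3248 genes in the joint tests of colon and dorsal horn, and 331, 735 and 492 genes in the tests between tissues. The colon joint test gave 4 genes with DESeq2 size factors and 4 without a filter. Only the 2 groups compared gave 7 colon genes for nivolumab against sham and 2 dorsal horn genes for cancer against sham, with fewer libraries behind the spread. The replicate block gave 1 colon and 115 dorsal horn genes for cancer against sham and 0 in the colon joint test. In these contrasts the numbers were not read as pairing the libraries, since same-numbered libraries of cancer and sham correlated at −0.240 to 0.458 in the colon and −0.0690 to 0.527 in the dorsal horn, with 2 of 3 over 0.1 in each and not every library closest to its own number, and the block ended the calls of Hbb-bs, Hba-a1 and Hba-a2, and of Slc4a1 for nivolumab against sham. For nivolumab against sham 1 of 3 pairs was over 0.1 in each tissue, and for nivolumab against cancer none was in the colon. Dorsal horn cancer and nivolumab correlated in all 3 pairs. There the block gave 3066 genes (2284 shared), and among the results given it changed no call other than those named beside them. With a block in the dorsal horn, 3, 71 and 33 genes differed between tissues (3, 18 and 18 shared). The calls of Dgat2 and Olfml2a for nivolumab against sham also ended.

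With an estimated correlation 0, 0 and 0 lists passed in the colon and 1, 0 and 1 in the dorsal horn, and fry passed 0, 0 and 0 and then 2, 9 and 4. With the ganglion covariate the dorsal horn counts were 389, 3126 and 2144 genes in the 3 contrasts (44, 1513 and 656 shared) and 2872 in the joint test. The ganglion list then had −0.42 against cancer and 0.020 against sham, which the covariate's construction gives, and the immediate early list was tested lower against sham (median 0.15). Without dorsal horn sham 3 and cancer 3 there were 91 genes for cancer against sham.

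Without colon sham 3 and cancer 2, the joint test gave 0 genes and 13 lists passed for nivolumab against cancer. For cancer against sham, Cd274 then had −0.26, oxidative phosphorylation 0.083 and enteric neurons −0.28. For nivolumab against cancer, Pdcd1lg2 had 0.023, endothelial markers −0.29 (tested higher) and enteric neurons 0.077.

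Leaving out 1 library at a time gave the following ranges in the colon. Genes numbered 0 to 9 for cancer against sham, 0 to 2 for nivolumab against cancer, 0 to 3 for nivolumab against sham and 0 to 7 in the joint test, and lists 12 to 24 for nivolumab against cancer. For cancer against sham, Cd274 ran from −0.062 to 0.65 and the interferon list from −0.19 to 0.41. For nivolumab against cancer, Pdcd1lg2 ran from −0.68 to 0.24 and enteric neurons from −1.44 to 0.065. For nivolumab against sham, cell cycle genes ran from −0.41 to 0.26, oxidative phosphorylation from −0.023 to 0.27 and smooth muscle from −1.72 to −0.19. The correlation of cancer against sham with nivolumab against cancer ran from −0.729 to −0.522, with a Spearman value of −0.677. In the dorsal horn the counts ran from 2 to 125, 771 to 2717 and 95 to 1237 genes in the 3 contrasts and from 452 to 2214 in the joint test, and that correlation from −0.667 to −0.174. The counts between tissues ran from 3 to 93, 1 to 138 and 3 to 48.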

Other observations

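No test was chosen for this part after the results were seen, and its values come from the planned tests, but its genes were picked after their values were seen. In the colon Reg4, Reg3g, Retnlb and Itln1 passed adjustment in no contrast. Reg4, a lectin of secretory cells, had 853, 2362 and 875 CPM in the sham libraries, 6.91, 0.827 and 3.88 in cancer and 29.7, 158 and 21.4 in nivolumab, with log2 fold changes of −8.46 for cancer against sham (adjusted p = 0.0748), 4.17 for nivolumab against cancer (adjusted p = 0.354) and −4.29 for nivolumab against sham (adjusted p = 0.417). Reg3g, an antimicrobial lectin, went the other way, with 227, 48.4 and 114 CPM in sham, 1873, 1888 and 1148 in cancer (3.66, adjusted p = 0.181) and 1462, 294 and 1729 in nivolumab (3.16 against sham, adjusted p = 0.417). Retnlb, an antimicrobial protein of goblet cells, was lowest with nivolumab, at 463 to 670.3 CPM against 1534 to 2524 in sham (−1.84, adjusted p = 0.331). Itln1, intelectin, had 2491 CPM in cancer 1 alone, 6.81 and 57.8 in the other cancer libraries, 70.8 to 102 in sham, so that cancer and sham overlapped, and 0.672 to 2.77 in nivolumab (−8.80 against cancer, adjusted p = 0.342).

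The tuft cell list had means of 3.42 to 3.54 log2 CPM in sham, 2.36 to 3.76 in cancer and 1.17 to 2.77 in nivolumab. Il6, an inflammatory cytokine, had 0 to 0.2002 CPM in sham, 0.199 to 1.78 in cancer and 2.08 to 3.61 in nivolumab (4.88 against sham, adjusted p = 0.372). Colon lists that passed in no contrast included absorptive colonocytes (median 0.31 for cancer against sham, adjusted p = 0.064), enteric glia (0.59, adjusted p = 0.0692) and the IL-17 and IL-22 axis (0.02, adjusted p = 0.531). In the dorsal horn, motor neuron (0.23, adjusted p = 0.361, but 0.0272 with the replicate block), ependymal (−0.22, adjusted p = 0.415) and meningeal markers (−0.11, adjusted p = 0.878) did not pass as lists without the block for nivolumab against cancer.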
